A study of Eremochloa ophiuroides with 12 samples.

How the data were processed

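Root RNA of centipedegrass (Eremochloa ophiuroides, cultivar Yuxi), a creeping warm-season turf grass, was measured by RNA sequencing in 4 groups. Per the labels, plants stood in pots of red soil to which cadmium chloride had been added to give 0, 50, 100 or 200 mg of cadmium per kg of soil; the groups are called CK, Cd50, Cd100 and Cd200. RNA was extracted with a column kit and libraries were made with a template-switching mRNA kit, per the labels' protocols. Whether reads carry their strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The labels do not say that the 3 samples of a group came from separate plants or pots. The p-values therefore measure only the spread between these samples, which may be technical.

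The values used are FPKM per gene and library, deposited by the authors as 1 table of 39697 genes. FPKM is the number of fragments per kilobase of gene and per 1e6 of a library total. HISAT2 was the aligner named, with no version, per the submitters' processing notes. Those notes also name GRCm38, a mouse build, while the deposited table names 9 chromosomes and 243 other sequences with identifiers that are not those of mouse. The assembly and annotation behind the coordinates are not given in the sources used here, and positions are printed as the table gives them. The other deposited quantity used, per the file headers, is gene length in bases, with a median of 1083. The authors' annotation text was present for 27882 genes (70.2%), and all gene names come from it by similarity to proteins of other species. A second deposited table holds the authors' mean FPKM per dose. Over genes above 0 these means equalled the mean of the 3 control libraries for 100% of genes, within a relative difference of 1e-06. At each cadmium dose they equalled the mean of the 3 libraries used here for 0% of genes. The authors' cadmium means therefore do not rest on these 3 libraries alone. Which columns gave them was not tested, and the means were not used.

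Of 15 per-sample columns, 12 were used, 3 per group. The other 3 per-sample columns, numbered 4 at each cadmium dose, match no sample title and were not used. Control columns are numbered 1, 3 and 4, which are not the numbers in the titles, so control libraries were assigned to their group alone. Cadmium columns were matched by dose and number, and that match could be off by the same renumbering.

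FPKM multiplied by gene length fell on whole multiples of 1 step per library for 100% of values, within 0.01 of a whole read, so read numbers could be recovered. The libraries held 12.42 to 17.71 M recovered reads (median 15.2; M is 1e6). A single read on a gene of 1 kb was worth 0.0528 to 0.088 FPKM, and 29300 to 31103 genes were above 0. The library total behind the authors' FPKM was not the sum of these reads. It was 0.771 to 0.915 times that sum in the control libraries and 0.888 to 1.12 times in the cadmium libraries, and how it was chosen is not given in the sources used here. This choice moves all genes of a library together and bears on the balance of higher against lower genes.

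Tests were run with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2(FPKM + 1) with no further normalization. The design, the gene lists and most alternatives were fixed before the data were examined. The 25723 genes (64.8%) with FPKM of at least 1 in at least 3 of the 12 libraries were tested. Group means were fitted over all 12 libraries, with eBayes variance shrinkage that follows mean expression, and the median standard error of a log2 change was 0.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. Each dose was compared with the control and with the other doses. A moderated F test asked whether any dose differed from the control, and a linear contrast over the dose order asked for a trend; both used the adjusted p alone. Errors are SD over 3 libraries for FPKM and the standard error of the fit for log2 changes.

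The 30 gene lists were formed by searching the annotation text for fixed words. They covered metal handling (metallothionein, phytochelatin and glutathione synthesis, heavy-metal ATPase, heavy-metal-associated domain, NRAMP/ZIP/cation efflux, strategy II iron acquisition, sulfur, ABC transporter), redox and glutathione S-transferase, phenylpropanoid, flavonoid, cell wall, hormone, transcription factor, stress, nutrient, ribosomal, cell cycle and, as a marker of shoot tissue, photosynthesis genes. Each list was tested against the other genes with camera (preset correlation 0.01, trended variance, Benjamini-Hochberg over the 30 lists); camera with an estimated correlation and fry were alternatives. Another 4 lists (core fermentation genes, clock genes, leaf-abundant transcripts, root surface and cortex genes) were made after the values were seen and serve only to describe libraries and in the closing tests.

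Genes named in the text followed a fixed rule. For each comparison with the control these were the 5 called genes with the largest rise and the 5 with the largest fall, given an informative annotation, a mean of at least 5 FPKM in the higher group, and all 3 cadmium libraries on one side of all 3 control libraries. For each list they were the 2 called members with the smallest adjusted p and at least 5 FPKM in the higher group, or, with none called, the member with the smallest p, given as values. The text gives list members for the metal (without ABC transporters), glutathione, antioxidant, class III peroxidase and phenylpropanoid lists. It also gives members for the lists that passed camera at a dose, other than the flavonoid list at Cd50. The remaining lists are given as counts.

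The fit was tested on simulated data: in 5 simulations of 25723 genes, 200 genes each were changed in Cd200 against the control. The fit called 16.4% of genes changed by 1 on the log2 scale, 78.8% at 2, 94.4% at 3 and 97.6% at 4. Changed genes were drawn from the better expressed ones, and noise was independent between genes. The 200 changed genes were also fewer than the 1882 to 2696 called against the control, so these shares need not hold for the real comparisons. The fold limit itself drops many genes changed by 1. Of 753 calls, 35 (4.65%) were unchanged genes, and the unchanged Cd50 group gave 0 calls. A missing call is therefore weak evidence for changes near 2-fold. Overlap between doses was set beside 20 simulations of unchanged groups against the same controls.

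The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, robust eBayes, the replicate number as a block, only the 2 groups compared, the adjusted p alone, and leaving out each library in turn. After the data were seen, rescaling by the sum of recovered reads, limma-voom on recovered reads, leaving out both Cd50 library 1 and Cd200 library 3, and camera without the trended variance were added. Tables were prepared with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) and drawn with matplotlib 3.10.9.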

Results

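Gene expression was measured in roots of centipedegrass, a turf grass, grown in soil with 0 (CK), 50 (Cd50), 100 (Cd100) or 200 (Cd200) mg/kg of added cadmium, with 3 libraries per group. Cadmium is a toxic metal with no known function in grasses, and the study asked how this grass tolerates it. The 12 libraries held 12.42 to 17.71 M recovered reads and 29300 to 31103 genes above 0, and 25723 genes were tested. Gene names are those of the most similar protein in the annotation, identifiers and positions are as deposited, and the assembly is not given in the sources used here.

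The roots without cadmium lay apart from all roots with cadmium. The first principal component held 33.5% of the variance and placed the control libraries between -105.5 and -74.2 and the cadmium libraries between -18.6 and 63.7. The doses overlapped on it, and Cd200 library 1, at -18.6, lay nearest the control. Correlations of log2(FPKM + 1) between libraries were 0.860 to 0.961 within groups and 0.804 to 0.959 between groups, and 0 pairs of libraries were identical. The second component (21.6%) set apart Cd50 library 1 at 116.7 and, less far, Cd200 library 3 at 40.6. Over 32 core fermentation genes (pyruvate decarboxylase, alcohol dehydrogenase and similar enzymes of sugar breakdown without oxygen), a list made after the values were seen, Cd50 library 1 summed to 19880 FPKM. Cd100 library 2 reached 9439, Cd200 library 3 reached 8693, and the remaining libraries lay between 2681 and 5859. Over 20 genes typical of the root surface and cortex, also listed after the values were seen, Cd50 library 1 summed to 248.9 and Cd200 library 3 to 1641 FPKM, while the remaining libraries lay between 2414 and 9500.

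**Figure D1:**
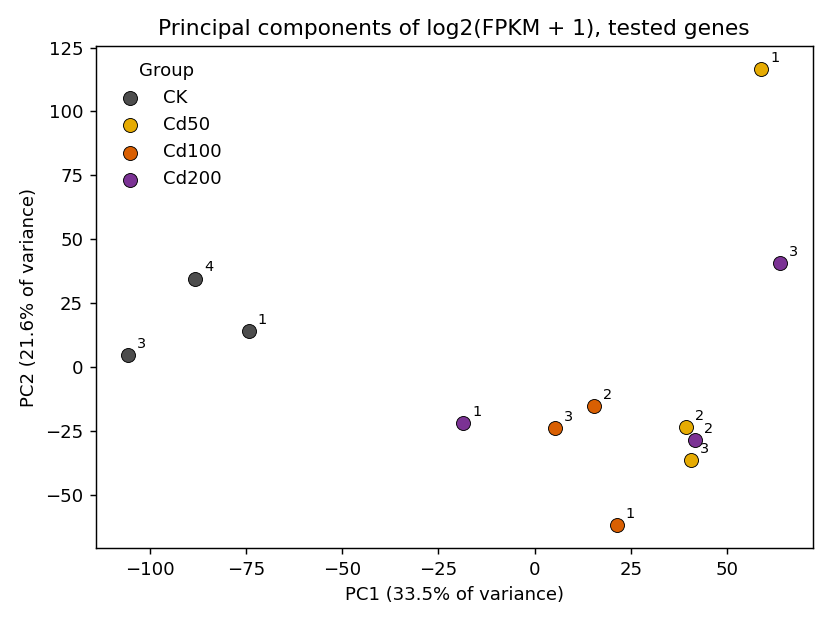
Each point is 1 root library, placed by its scores on the first and second principal components of log2(FPKM + 1) over the tested genes; colours give the soil cadmium group and numbers the library. The 3 control libraries lie at -74.2 or below on the first component and the 9 cadmium libraries at -18.6 or above, and Cd50 library 1 lies apart at 116.7 on the second.

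At 50 mg/kg cadmium, Metallothionein-like protein 4B and a pair of carboxylesterase genes were among the 5 largest rises by the rule for named genes, and DREB1F, REVEILLE 4 and REVEILLE 3 among the 5 largest falls. Metallothionein-like protein 4B (evm.TU.ctg435.71, chromosome 3, 61218650 to 61219146), a small cysteine-rich protein of a family that binds metal ions, rose from 46.3 ± 20.1 FPKM in CK to 918 ± 601 in Cd50 (SD, n = 3 each; log2 change 4.09 ± 0.68, adjusted p = 0.006). A pair of neighbouring genes named Probable carboxylesterase 15 rose, evm.TU.ctg261.2 (chromosome 2, 10238249 to 10239517) from 4.28 ± 1.63 to 92.3 ± 30.0 FPKM and evm.TU.ctg261.1 (10250129 to 10251512) from 9.70 ± 6.04 to 127 ± 55.0. As similar copies they may share reads. Light-regulated protein (evm.TU.ctg17.103, chromosome 5, 16811469 to 16812161) rose by 3.79 ± 0.46 on the log2 scale. Cytochrome P450 71A4 (a gene model without an evm identifier, chromosome 5, 1275017 to 1277351) rose by 3.66 ± 0.50, from 0.158 to 13.9 FPKM. Dehydration-responsive element-binding protein 1F (DREB1F, evm.TU.ctg69.74, chromosome 5, 85434674 to 85435342), of a family of cold and drought response regulators, fell from 1003 ± 259 to 33.2 ± 11.6 FPKM (log2 change -4.89 ± 0.67, adjusted p = 0.0039). The clock-related MYB factor REVEILLE 4 (evm.TU.ctg9.262, chromosome 5, 9643501 to 9645065) fell from 354 ± 136 to 3.33 ± 1.11 FPKM. REVEILLE 3 (evm.TU.ctg374.103, chromosome 1, 18985963 to 18986520) fell from 65.0 ± 49.8 to 0.582 ± 0.408. Lecithin-cholesterol acyltransferase-like 1 (evm.TU.ctg239.3, chromosome 2, 35155835 to 35157221) fell from 1198 ± 583 to 30.9 ± 19.97 FPKM. Ent-copalyl diphosphate synthase AN1 (evm.TU.ctg355.43, chromosome 1, 41581722 to 41586932), of the enzyme class that opens gibberellin synthesis, fell from 58.0 ± 16.9 to 0.570 ± 0.479 FPKM. Adjusted p was 0.006 or lower for each of these 10 genes, and all 3 Cd50 libraries lay on one side of all 3 control libraries, as the rule for naming them required.

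Of 6 metallothioneins tested, 3 rose and 0 fell at Cd50 (3 and 0 adjusted over the list alone), and the list stood above the other genes in camera (adjusted p = 0.00365; adjusted p = 0.929 with an estimated correlation). Besides 4B, Class II metallothionein-like protein 1A (evm.TU.ctg314.81, chromosome 1, 78609898 to 78610146) rose from 1.15 ± 1.49 to 6.71 ± 2.44 FPKM, a call lost with only CK and Cd50 in the fit (adjusted p = 0.059). Among 47 heavy-metal-associated domain proteins 5 rose and 3 fell (5 and 4 adjusted over the list alone), with rises of isoprenylated protein 44 (evm.TU.ctg278.37, chromosome 1, 112767477 to 112768688) from 8.51 ± 1.53 to 40.6 ± 8.24 FPKM. Isoprenylated protein 33 (evm.TU.ctg63.125, chromosome 5, 82592637 to 82594161) rose from 7.503 ± 0.446 to 29.4 ± 13.4. Of 15 heavy-metal ATPases, pumps that move metal ions across membranes, 2 rose and 1 fell (2 and 2 adjusted over the list alone; 4 and 1 without Cd50 library 1). Copper-transporting ATPase PAA2 (evm.TU.ctg286.25, chromosome 1, 106867619 to 106874839) fell from 88.9 ± 18.3 to 15.5 ± 4.54 FPKM, with adjusted p = 0.054 without control library 3. Copper-transporting ATPase HMA4 (evm.TU.ctg697.80, chromosome 6, 14051906 to 14052769) rose from 25.3 ± 4.09 to 82.7 ± 46.9. A neighbouring gene of the same name may share reads with it or be part of the same gene. Among 35 NRAMP, ZIP and cation efflux transporters 2 rose and 0 fell (2 and 0 adjusted over the list alone; 5 and 0 after rescaling by read sums; 4 and 1 without Cd50 library 1). Metal transporter Nramp2 (evm.TU.ctg286.286, chromosome 1, 103857879 to 103861902) rose from 5.17 ± 3.64 to 27.9 ± 16.6 FPKM. The HMA4 and Nramp2 calls were each lost without control library 3 or 4 or without Cd50 library 2 or 3, and that of HMA4 also without control library 1. Both were lost with only CK and Cd50 in the fit and that of HMA4 with no filter, with adjusted p over all alternatives up to 0.13 for HMA4 and 0.11 for Nramp2. In the strategy II iron list (synthesis and transport of the iron chelators of grasses) 3 of 40 rose and 2 fell (3 and 2 adjusted over the list alone; 5 and 0 after rescaling by read sums; 5 and 3 without Cd50 library 1). Metal-nicotianamine transporter YSL16 (evm.TU.ctg780.42, chromosome 8, 53352270 to 53355574) rose from 7.84 ± 2.34 to 49.6 ± 32.0 FPKM (adjusted p = 0.013; 0.056 without control library 3). Nicotianamine aminotransferase 1 (evm.TU.ctg1038.1, sequence SS_121_F_6_D, 7965 to 10823) rose from 19.3 ± 3.75 to 58.7 ± 17.7, a call lost without any single control library or without Cd50 library 2 or 3 (adjusted p up to 0.083). The phytochelatin and glutathione synthesis list had 0 of 6 genes called (0 adjusted over the list alone). Without Cd50 library 1 it had 0 higher and 1 lower, and without both Cd50 library 1 and Cd200 library 3 it had 1 and 1. Its smallest p was that of Glutathione synthetase (evm.TU.ctg174.60, chromosome 4, 94143639 to 94149325) at 3.32 ± 0.512 FPKM in CK and 8.79 ± 4.25 in Cd50 (adjusted p = 0.18).

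Glutathione S-transferases, which join glutathione to reactive or foreign compounds, had 5 of 93 higher and 5 lower at Cd50 (5 and 5 adjusted over the list alone; 9 and 4 after rescaling by read sums; 7 and 4 without Cd50 library 1). GSTU6 (evm.TU.ctg52.158, chromosome 5, 62131791 to 62132622) rose from 41.6 ± 18.1 to 446 ± 118 FPKM. A gene annotated only by its transferase domain (evm.TU.ctg587.49, chromosome 9, 55702831 to 55705430) fell from 93.7 ± 18.3 to 32.7 ± 4.58. The median (-0.09) and mean (0.02) log2 change of this list differed in sign. Of 35 sulfur uptake and assimilation genes 1 rose and 4 fell (1 and 5 adjusted over the list alone; 4 and 2 after rescaling by read sums). Sulfate transporter 3.1 (evm.TU.ctg280.237, chromosome 1, 108966589 to 108972240) fell from 52.5 ± 32.6 to 7.04 ± 1.55 FPKM. Sulfate transporter 1.3 (evm.TU.ctg589.102, chromosome 9, 44171182 to 44176422) fell from 11.2 ± 1.35 to 4.77 ± 0.280, and this change came under 2-fold after rescaling by read sums or with limma-voom. Antioxidant enzymes had 3 of 41 higher and 3 lower (3 and 3 adjusted over the list alone). They had 4 and 1 after rescaling by read sums, 2 and 0 without Cd50 library 1, and 3 and 3 without both Cd50 library 1 and Cd200 library 3. Catalase isozyme 3 (evm.TU.ctg710.97, chromosome 6, 1496858 to 1502118), an enzyme that breaks down hydrogen peroxide, rose from 37.5 ± 10.9 to 163.5 ± 72.0 FPKM. Probable L-ascorbate peroxidase 4 (evm.TU.ctg584.77, chromosome 9, 57606400 to 57610129) rose from 57.2 ± 8.90 to 129.9 ± 13.0.

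Of 84 jasmonate genes at Cd50, 1 rose and 27 fell (2 and 33 adjusted over the list alone; camera adjusted p = 5.2e-08; adjusted p = 0.929 with an estimated correlation). TIFY 11e (evm.TU.ctg350.19, chromosome 1, 47419196 to 47419432) and TIFY 9 (evm.TU.ctg1137.1, sequence SS_51_F_2_D, 81480 to 84085), of the family of jasmonate repressors, fell from 389 ± 159 to 14.5 ± 8.22 and from 26.0 ± 5.74 to 5.65 ± 0.638 FPKM. Of 209 cell wall genes 3 rose and 49 fell (9 and 55 adjusted over the list alone; camera adjusted p = 4.32e-04; adjusted p = 0.929 with an estimated correlation). Expansin-B3 (evm.TU.ctg315.80, chromosome 1, 76703389 to 76705100) fell from 12.2 ± 4.73 to 0.376 ± 0.467 FPKM, and xyloglucan glycosyltransferase 7 (evm.TU.ctg565.166, chromosome 7, 64463969 to 64467982) from 50.8 ± 13.0 to 10.9 ± 0.634. Of 143 phenylpropanoid and lignin genes 1 rose and 23 fell (1 and 29 adjusted over the list alone; camera adjusted p = 0.00155; adjusted p = 0.929 with an estimated correlation). Dirigent protein 21 (evm.TU.ctg89.15, chromosome 4, 21039189 to 21040107) fell from 44.2 ± 17.5 to 2.44 ± 0.808 FPKM. The single riser was Cinnamoyl-CoA reductase-like SNL6 (evm.TU.ctg317.31, chromosome 1, 70530707 to 70533787), from 11.97 ± 0.667 to 54.2 ± 8.02. Flavonoid genes showed 3 of 95 higher and 17 lower (3 and 21 adjusted over the list alone; camera adjusted p = 0.0135; adjusted p = 0.929 with an estimated correlation). Class III peroxidases, enzymes of the cell wall, had 1 of 88 higher and 8 lower (1 and 7 adjusted over the list alone; camera adjusted p = 0.0184; adjusted p = 0.929 with an estimated correlation). Peroxidase 2 (evm.TU.ctg182.106, chromosome 2, 104817980 to 104819834) fell from 23.0 ± 18.4 to 0.871 ± 0.657 FPKM. Peroxidase 55 (evm.TU.ctg581.34, chromosome 9, 60629143 to 60631751) fell from 307 ± 91.0 to 51.7 ± 32.9 (adjusted p = 0.052 without control library 3). After rescaling by read sums the jasmonate list had 2 higher and 19 lower, the cell wall list 15 and 40, the phenylpropanoid list 3 and 18, the flavonoid list 4 and 10 and the peroxidases 3 and 8. Cd50 library 1, with 248.9 FPKM summed over the root surface and cortex genes, bore on these 5 lists. Without it the cell wall list had 17 higher and 32 lower and the phenylpropanoid list 7 and 18. Likewise without it the flavonoid list had 6 and 13, the peroxidases 7 and 5, and the jasmonate list 2 and 22.

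Of 338 ribosomal protein genes at Cd50, 5 rose and 0 fell (2 and 0 adjusted over the list alone; 26 and 0 after rescaling by read sums), with a median log2 change of 0.40 (camera adjusted p = 3.47e-08; adjusted p = 0.929 with an estimated correlation). 40S ribosomal protein S25-2 (evm.TU.ctg640.53, chromosome 6, 64575054 to 64577323) rose from 0.823 ± 0.162 to 8.71 ± 1.36 FPKM. The chloroplast 50S protein L1 (evm.TU.ctg551.16, chromosome 7, 50542973 to 50551983) rose from 8.31 ± 1.89 to 26.7 ± 1.81. Photosynthesis genes, a marker of shoot tissue, had 7 of 31 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.00698, 0.0596 after rescaling by read sums; adjusted p = 0.929 with an estimated correlation). Their levels were low: Oxygen-evolving enhancer protein 2 (evm.TU.ctg265.102, chromosome 2, 7420065 to 7421388) rose from 6.83 ± 0.879 to 21.6 ± 7.18 FPKM. Photosystem II reaction center W protein (evm.TU.ctg56.29, chromosome 5, 69432713 to 69433591) fell from 6.86 ± 1.11 to 2.08 ± 0.693.

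Among the transcription factor lists at Cd50, 19 of 224 MYB genes rose and 21 fell (20 and 26 adjusted over the list alone). Of the NAC genes, 10 of 93 rose and 7 fell (10 and 7). Of the WRKY genes, 5 of 92 rose and 16 fell (8 and 23). Ethylene genes had 7 of 154 higher and 16 lower (7 and 17 adjusted over the list alone). Abscisic acid and dehydration genes had 3 of 88 higher and 16 lower (4 and 16). Auxin genes had 9 of 133 higher and 12 lower (10 and 13). Pathogenesis-related proteins and chitinases had 7 of 121 higher and 10 lower (12 and 13 adjusted over the list alone). Heat shock proteins and chaperones had 5 of 222 higher and 12 lower (4 and 11). ABC transporters had 5 of 121 higher and 8 lower (5 and 8). Nitrate genes had 5 of 102 higher and 10 lower (5 and 14 adjusted over the list alone). Phosphate starvation genes had 3 of 70 higher and 6 lower (3 and 6). Aquaporins had 2 of 29 higher and 2 lower (2 and 2). Histone and cell cycle genes had 3 of 219 higher and 8 lower (3 and 8 adjusted over the list alone). Hypoxia and fermentation genes had 0 of 44 higher and 4 lower (0 and 4 adjusted over the list alone) beside the 19880 FPKM that Cd50 library 1 reached over the core fermentation genes. After rescaling by read sums the balance of several of these lists turned or evened out. Higher and lower genes then numbered 31 and 17 for MYB, 12 and 12 for WRKY, 15 and 6 for auxin, 13 and 13 for ethylene and 14 and 9 for pathogenesis-related proteins. They numbered 12 and 5 for ABC transporters, 10 and 8 for heat shock proteins, 8 and 6 for nitrate, 5 and 3 for phosphate starvation, 4 and 0 for aquaporins and 11 and 4 for histone and cell cycle genes. For NAC genes they numbered 13 and 4, for abscisic acid genes 9 and 15 and for hypoxia and fermentation genes 0 and 2. Without Cd50 library 1, pathogenesis-related proteins had 15 higher and 10 lower, abscisic acid genes 10 and 15, ethylene genes 14 and 18, auxin genes 12 and 10, MYB genes 20 and 19, WRKY genes 9 and 13, nitrate genes 9 and 11 and aquaporins 4 and 1.

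In all, limma called 2696 genes at Cd50, 906 higher and 1790 lower (33.6% higher). Dividing each library by its recovered reads in place of the authors' total raised the median log2 change of all genes to 0.31 at Cd50, 0.24 at Cd100 and 0.17 at Cd200. The split at Cd50 became 2250 higher and 1175 lower (65.7% higher). With limma-voom, which took the same read sums as library totals, 68% of calls were higher. The balance of all calls depended on how the libraries were scaled. With median-ratio rescaling 33.9%, 41.2% and 49.1% of calls were higher at Cd50, Cd100 and Cd200. With quantile normalization the shares were 43.5%, 44.5% and 50.9%. The count was 1265 without control library 3, 1591 without control library 4 and 1604 without Cd50 library 2.

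At 100 mg/kg cadmium the largest rise by the rule for named genes was that of Copper transport protein CCH (evm.TU.ctg657.18, chromosome 6, 50343074 to 50344418). This heavy-metal-associated domain protein, named after a copper chaperone, rose from 1.82 ± 0.269 FPKM in CK to 323 ± 90.5 in Cd100 (SD, n = 3 each, log2 change 6.81 ± 0.80, adjusted p = 0.004). Metallothionein-like protein 4B rose to 1211 ± 403 FPKM (log2 change 4.74 ± 0.68, adjusted p = 0.0056). A pair of early light-inducible proteins, which bind pigments in stressed chloroplasts, rose with a wide spread. HV58 (evm.TU.ctg257.29, chromosome 2, 13327306 to 13327864) rose from 1.73 ± 1.58 to 132 ± 131 FPKM. HV90 (evm.TU.ctg257.25, 13358644 to 13359219) rose from 2.31 ± 1.52 to 120.1 ± 111. As members of a gene cluster they may share reads. Pathogenesis-related thaumatin-like protein 3.2 (evm.TU.ctg374.71, chromosome 1, 19277782 to 19278435) rose from 11.2 ± 6.53 to 225 ± 86.0 FPKM, a call lost without control library 1 or 3 or without Cd100 library 1 or 2 (adjusted p up to 0.064). DREB1F fell to 30.3 ± 19.1 FPKM (log2 change -5.18 ± 0.67), and REVEILLE 4 to 11.2 ± 0.799 (-4.79 ± 0.76). Ethylene-responsive transcription factor ERF109 (evm.TU.ctg587.209, chromosome 9, 53114402 to 53115226) fell from 654 ± 72.7 to 31.5 ± 15.5 (-4.44 ± 0.67). A pair of genes for Cystathionine gamma-synthase 1, an enzyme of methionine synthesis, fell, evm.TU.ctg351.26 (chromosome 1, 45063964 to 45065453) from 170.4 ± 61.5 to 5.14 ± 2.27 FPKM and evm.TU.ctg351.28 (44957885 to 44959374) from 65.8 ± 15.5 to 2.27 ± 1.45. Both calls were lost without control library 4 or Cd100 library 1, and the former also without control library 3 (adjusted p up to 0.073 and 0.058), and the copies may share reads.

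Metal genes at Cd100 included 2 of 6 metallothioneins higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.0136; adjusted p = 0.825 with an estimated correlation). The second was Class II metallothionein-like protein 1A, at 6.24 ± 0.958 FPKM (adjusted p = 0.017; up to 0.067 without control library 3 or 4 or Cd100 library 1 or 2, each of which ended the call). Of 47 heavy-metal-associated domain proteins 5 rose and 3 fell (6 and 7 adjusted over the list alone; 8 and 5 without Cd50 library 1, which enters the variance of the fit), isoprenylated protein 44 reaching 40.2 ± 4.33 FPKM. Both neighbouring genes named HMA4 were called among 15 heavy-metal ATPases (2 higher, 0 lower). The list had 4 and 0 adjusted over the list alone and 4 and 0 without Cd50 library 1. The HMA4 genes were evm.TU.ctg697.80 at 101 ± 20.9 FPKM and evm.TU.ctg697.81 (chromosome 6, 14049498 to 14051380) rising from 11.5 ± 4.27 to 48.1 ± 14.9. Whether they are separate genes or parts of a single gene was not tested, so the 2 calls may count a single locus. Leaving out control library 3 or 4 or any single Cd100 library ended both calls (adjusted p up to 0.071 and 0.12). The NRAMP, ZIP and cation efflux list had 2 of 35 higher and 0 lower (2 and 0 adjusted over the list alone). Nramp2 reached 42.5 ± 19.2 FPKM. Zinc transporter 1 (evm.TU.ctg69.93, chromosome 5, 85585643 to 85586677) went from 0.208 ± 0.0729 to 7.33 ± 3.05. Both calls were lost without control library 4 or Cd100 library 1 and the latter also without control library 3 or Cd100 library 3 or with limma-voom (adjusted p over all alternatives up to 0.07 and 0.071). In the strategy II iron list 2 of 40 rose and 0 fell (2 and 0 adjusted over the list alone). YSL16 reached 150.2 ± 78.6 FPKM (log2 change 4.01 ± 0.49, adjusted p = 0.0045), and YSL14 (evm.TU.ctg640.187, chromosome 6, 62916559 to 62921034) rose from 4.58 ± 0.105 to 14.8 ± 3.996, a call lost without control library 3 or 4 or Cd100 library 1 or 3 (adjusted p up to 0.077). The phytochelatin and glutathione synthesis list had 0 of 6 called (0 adjusted over the list alone), its smallest p being that of Glutathione gamma-glutamylcysteinyltransferase 1, a phytochelatin synthase (evm.TU.ctg6.27, chromosome 5, 3501077 to 3504731), at 17.0 ± 1.56 FPKM in CK and 9.05 ± 0.423 in Cd100 (adjusted p = 0.054).

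Of 93 glutathione S-transferases at Cd100, 4 rose and 3 fell (4 and 3 adjusted over the list alone; 7 and 3 after rescaling by read sums). IN2-1 homolog B (evm.TU.ctg293.132, chromosome 1, 96358873 to 96374279) rose from 2.43 ± 0.930 to 50.5 ± 12.9 FPKM and GSTU6 to 295 ± 132. The sulfur list had 0 of 35 higher and 1 lower (0 and 0 adjusted over the list alone; 1 and 0 after rescaling by read sums). That gene was a Ferredoxin-nitrite reductase (evm.TU.ctg630.24, chromosome 6, 76258159 to 76261629), an enzyme of nitrogen rather than sulfur assimilation that the text search took in. It fell from 124 ± 28.8 to 22.7 ± 10.98 FPKM, and leaving out any single library of the CK or Cd100 group ended the call, as did no filter, quantile normalization, rescaling by read sums and limma-voom (adjusted p over all alternatives up to 0.15). Antioxidant enzymes had 1 of 41 higher and 1 lower (1 and 1 adjusted over the list alone; 4 and 1 after rescaling by read sums). Catalase isozyme 3 reached 157 ± 47.8 FPKM, a call lost without control library 4 or Cd100 library 1 or 3 (adjusted p up to 0.07). Glutathione reductase (evm.TU.ctg355.45, chromosome 1, 41509712 to 41513523) fell from 7.99 ± 3.05 to 2.49 ± 0.595 (adjusted p = 0.058 without Cd100 library 1). Class III peroxidases had 1 of 88 higher and 2 lower (0 and 0 adjusted over the list alone; 4 and 4 without Cd50 library 1). Peroxidase 55 fell to 62.7 ± 13.0 FPKM and Peroxidase 2 to 3.11 ± 2.65. The Peroxidase 55 call was lost without control library 3 or 4 or any single Cd100 library, and that of Peroxidase 2 without control library 1 or 4 or Cd100 library 1 or 3. The Peroxidase 2 call was also lost with a pseudocount of 0.1, with no filter, with only CK and Cd100 in the fit and with limma-voom (adjusted p over all alternatives up to 0.11 and 0.13). Phenylpropanoid genes had 2 of 143 higher and 9 lower (2 and 9 adjusted over the list alone; 5 and 10 without Cd50 library 1; 5 and 7 after rescaling by read sums), SNL6 reaching 55.4 ± 4.98 FPKM. Cinnamoyl-CoA reductase 1 (evm.TU.ctg18.53, chromosome 5, 18382730 to 18387192) fell from 27.9 ± 10.3 to 1.35 ± 0.814 (adjusted p = 0.0081; 0.051 with a pseudocount of 0.1).

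Of 84 jasmonate genes at Cd100, 2 rose and 12 fell (3 and 17 adjusted over the list alone; 3 and 8 after rescaling by read sums). Camera gave adjusted p = 0.0016, with adjusted p = 0.825 with an estimated correlation. TIFY 11d (evm.TU.ctg350.21, chromosome 1, 47393599 to 47394090) fell to 235 ± 58.6 FPKM (log2 change -2.99 ± 0.52) and TIFY 11e to 27.1 ± 6.79. Photosynthesis genes had 5 of 31 higher and 0 lower (5 became 6 adjusted over the list alone; camera adjusted p = 0.0136; adjusted p = 0.825 with an estimated correlation). The called photosynthesis genes with the smallest p were early light-inducible proteins, HV90 and its copy evm.TU.ctg257.34 (chromosome 2, 13240135 to 13241921), the latter at 0.856 ± 0.253 FPKM in CK and 20.4 ± 20.4 in Cd100. Flavonoid genes had 2 of 95 higher and 9 lower (2 and 10 adjusted over the list alone). Cell wall genes had 7 of 209 higher and 10 lower (9 and 11). Ribosomal protein genes had 4 of 338 higher and 0 lower (2 and 0). Among transcription factors 18 of 224 MYB genes rose and 14 fell (23 and 18 adjusted over the list alone). Of the NAC genes, 5 of 93 rose and 4 fell (8 and 5). Of the WRKY genes, 5 of 92 rose and 13 fell (5 and 16). Ethylene genes had 13 of 154 higher and 12 lower (17 and 16 adjusted over the list alone). Abscisic acid and dehydration genes had 4 of 88 higher and 8 lower (7 and 12). Auxin genes had 6 of 133 higher and 4 lower (5 and 4). Pathogenesis-related proteins and chitinases had 5 of 121 higher and 2 lower (6 and 3 adjusted over the list alone). Heat shock proteins and chaperones had 5 of 222 higher and 9 lower (4 and 8). ABC transporters had 6 of 121 higher and 5 lower (6 and 5). Nitrate genes had 3 of 102 higher and 7 lower (3 and 7 adjusted over the list alone). Phosphate starvation genes had 6 of 70 higher and 3 lower (6 and 3). Aquaporins had 2 of 29 higher and 1 lower (5 and 1). Histone and cell cycle genes had 2 of 219 higher and 6 lower (1 and 5 adjusted over the list alone). Hypoxia and fermentation genes had 0 of 44 higher and 2 lower (0 and 2), beside 9439 FPKM over the core fermentation genes in Cd100 library 2. After rescaling by read sums, higher and lower genes numbered 7 and 3 for heat shock proteins, 10 and 9 for the cell wall, 5 and 4 for histone and cell cycle, 7 and 7 for WRKY, 3 and 3 for nitrate and 14 and 1 for pathogenesis-related proteins. They numbered 10 and 3 for NAC, 26 and 12 for MYB, 8 and 2 for auxin, 7 and 8 for abscisic acid and 5 and 1 for aquaporins. Likewise they numbered 7 and 2 for ABC transporters, 3 and 5 for flavonoid and 7 and 0 for ribosomal protein genes. With Cd50 library 1 left out, pathogenesis-related proteins had 12 higher and 4 lower at Cd100, auxin genes 10 and 8, nitrate genes 7 and 10 and cell wall genes 12 and 12. Abscisic acid genes then had 6 and 13, NAC genes 8 and 6 and aquaporins 5 and 1.

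At Cd100 limma called 1882 genes, 768 higher and 1114 lower (40.8% higher), and after rescaling by read sums 1372 higher and 722 lower (65.5% higher; 65% with limma-voom). The count was 891 without control library 3, 682 without control library 4, 491 without Cd100 library 1 and 1026 without Cd100 library 2.

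**Figure D2:**
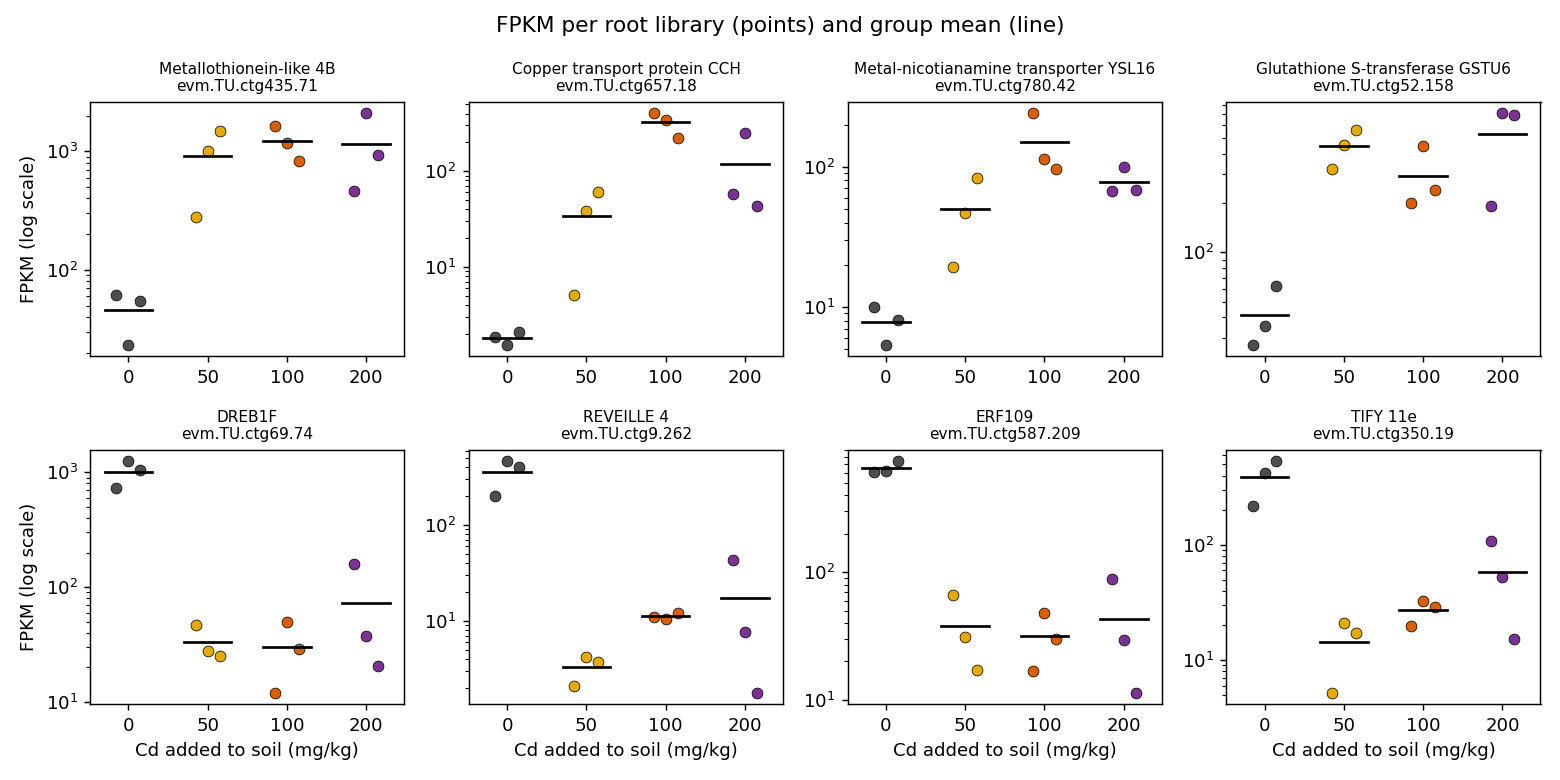
FPKM (log scale) of 8 genes against the cadmium added to the soil in mg/kg; points are the 3 libraries of each group and lines the group means. Metallothionein-like 4B lies between 23.4 and 61.3 FPKM in the control libraries and between 279 and 2085 in the cadmium libraries, and DREB1F between 728 and 1243 in the control and between 12.1 and 161 with cadmium.

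At 200 mg/kg cadmium, CCH, Metallothionein-like protein 4B and a pathogenesis-related protein were among the largest rises by the rule for named genes. The fallen regulators DREB1F, REVEILLE 4 and ERF109 were again among the largest falls by that rule. CCH stood at 118 ± 116 FPKM in Cd200 (SD, n = 3; log2 change 4.96 ± 0.80, adjusted p = 0.0057) and Metallothionein-like protein 4B at 1158 ± 836 (4.46 ± 0.68, adjusted p = 0.0049). A gene named Pathogenesis-related protein 1 (evm.TU.ctg267.33, chromosome 2, 6039473 to 6040241), after a defence marker, rose from 28.7 ± 14.3 to 477 ± 63.2 FPKM (adjusted p = 0.0011). Another gene of that name (evm.TU.ctg571.7) went the other way. It lay at 47.8 to 152.9 FPKM in the control libraries and 2.50 to 13.6 in the Cd200 libraries, and was called lower at Cd50. A VQ motif gene (evm.TU.ctg448.15, chromosome 3, 36863124 to 36863540), of a family of WRKY partner proteins, rose from 6.67 ± 0.817 to 229.7 ± 89.3 (adjusted p = 9.9e-04). Cysteine-rich repeat secretory protein 55 (evm.TU.ctg293.67, chromosome 1, 97061528 to 97062435) rose from 8.47 ± 11.8 to 141 ± 156 FPKM, a call lost without control library 1 or 3 or Cd200 library 2 or 3, with no filter, with only CK and Cd200 in the fit or with limma-voom (adjusted p over all alternatives up to 0.14). DREB1F fell to 73.1 ± 76.3 FPKM, ERF109 to 43.3 ± 40.6 and REVEILLE 4 to 17.5 ± 22.4. P-(S)-hydroxymandelonitrile lyase (evm.TU.ctg142.17, chromosome 4, 70706786 to 70710912), named after a sorghum enzyme that releases cyanide, fell from 72.3 ± 51.7 to 2.08 ± 1.64 FPKM. Ent-copalyl diphosphate synthase AN1 fell to 2.51 ± 2.45 (log2 change -4.35 ± 0.54).

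Of 6 metallothioneins at Cd200, 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 1.93e-04; adjusted p = 0.498 with an estimated correlation). Without Cd50 library 1 and Cd200 library 3 the number was 3. Metallothionein-like protein 1 (evm.TU.ctg594.35, chromosome 9, 28879979 to 28880466) rose from 6.09 ± 2.27 to 24.0 ± 3.28 FPKM. Of 47 heavy-metal-associated domain proteins 7 rose and 3 fell (7 and 3 adjusted over the list alone), isoprenylated protein 44 reaching 46.3 ± 17.8 FPKM. Among 15 heavy-metal ATPases 1 rose and 1 fell (2 and 3 adjusted over the list alone; 3 and 1 after rescaling by read sums). Copper-transporting ATPase HMA5 (evm.TU.ctg780.144, chromosome 8, 54747552 to 54754807) rose from 2.51 ± 1.51 to 27.2 ± 21.8 FPKM and PAA2 fell to 20.9 ± 17.7. Both calls were lost without control library 3 or 4 or Cd200 library 2, that of HMA5 also without Cd200 library 3 and that of PAA2 with only CK and Cd200 in the fit (adjusted p over all alternatives up to 0.12 and, for PAA2, 0.063). The NRAMP, ZIP and cation efflux list had 2 of 35 higher and 0 lower (3 and 1 adjusted over the list alone; 4 and 0 after rescaling by read sums). Metal tolerance protein 7 (evm.TU.ctg11.90, chromosome 5, 12684667 to 12691886) rose from 24.9 ± 4.63 to 57.5 ± 9.63 FPKM and Nramp2 to 27.1 ± 8.44. In the strategy II iron list 4 of 40 rose and 0 fell (4 and 0 adjusted over the list alone). YSL16 reached 78.4 ± 18.3 FPKM (log2 change 3.18 ± 0.49). Nicotianamine synthase 3 (evm.TU.ctg374.18, chromosome 1, 19984079 to 19985632) rose from 3.06 ± 2.95 to 17.6 ± 4.64. The Nramp2 and Nicotianamine synthase 3 calls were each lost without control library 3 or 4 or Cd200 library 2 or 3 (adjusted p up to 0.095 for both). The phytochelatin and glutathione synthesis list had 0 of 6 higher and 1 lower (0 and 2 adjusted over the list alone). The phytochelatin synthase evm.TU.ctg6.27 fell from 17.0 ± 1.56 to 7.91 ± 0.520 FPKM (adjusted p = 0.024). This call was lost without any single control library, without Cd200 library 2 or 3 or both Cd50 library 1 and Cd200 library 3, after rescaling by read sums and with limma-voom (adjusted p over all alternatives up to 0.081).

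Of 93 glutathione S-transferases 5 rose and 3 fell at Cd200 (5 and 3 adjusted over the list alone; 8 and 3 without Cd50 library 1 and Cd200 library 3), GSTU6 reaching 530.3 ± 293 FPKM and the transferase-domain gene evm.TU.ctg587.49 falling to 32.9 ± 11.4. The sulfur list had 3 of 35 higher and 0 lower (3 and 0 adjusted over the list alone). Both examples belong to cysteine synthesis. Probable serine acetyltransferase 5 (evm.TU.ctg567.3, chromosome 7, 66557705 to 66559025) rose from 18.1 ± 1.95 to 40.9 ± 6.60 FPKM. Cysteine synthase (evm.TU.ctg469.14, chromosome 3, 11710815 to 11713649) rose from 6.43 ± 2.13 to 19.3 ± 5.23. Antioxidant enzymes had 2 of 41 higher and 1 lower (2 and 1 adjusted over the list alone), Catalase isozyme 3 reaching 183 ± 74.7 FPKM and L-ascorbate peroxidase 4 127 ± 24.5. Class III peroxidases had 2 of 88 higher and 4 lower (2 and 4 adjusted over the list alone; 7 and 6 without Cd50 library 1; 7 and 4 without Cd50 library 1 and Cd200 library 3). Cationic peroxidase SPC4 (evm.TU.ctg69.16, chromosome 5, 84988360 to 84990487) rose from 43.9 ± 24.2 to 272 ± 103 FPKM. Peroxidase 2 fell to 1.71 ± 1.05 (adjusted p = 0.061 without Cd200 library 3). Phenylpropanoid genes had 4 of 143 higher and 11 lower (4 and 11 adjusted over the list alone; 9 and 14 without Cd50 library 1; 7 and 8 without Cd50 library 1 and Cd200 library 3; 7 and 10 after rescaling by read sums), SNL6 reaching 62.7 ± 31.4 FPKM and Cinnamoyl-CoA reductase 1 falling to 1.42 ± 1.29.

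Of 84 jasmonate genes at Cd200, 1 rose and 15 fell (1 and 19 adjusted over the list alone; camera adjusted p = 1.93e-04; adjusted p = 0.888 with an estimated correlation). Without Cd50 library 1 and Cd200 library 3 they numbered 4 and 11, and after rescaling by read sums 1 and 14. Linoleate 9S-lipoxygenase 4 (evm.TU.ctg376.107, chromosome 1, 15926528 to 15933448), of a class of enzymes that oxidise fatty acids, fell from 12.3 ± 3.80 to 2.37 ± 1.55 FPKM. Increased DNA methylation 1 (evm.TU.ctg761.189, chromosome 8, 40736420 to 40744089), a histone acetyltransferase in thale cress that the list took in through a domain name, fell from 12.2 ± 1.999 to 3.80 ± 0.727. Cell wall genes had 9 of 209 higher and 18 lower (10 and 21 adjusted over the list alone; camera adjusted p = 0.0361; adjusted p = 0.888 with an estimated correlation). Xyloglucan glycosyltransferase 7 fell to 14.03 ± 5.02 FPKM. A Probable polygalacturonase (evm.TU.ctg488.14, chromosome 3, 1288753 to 1292218) rose from 8.94 ± 4.26 to 40.8 ± 12.2. Leaving out Cd50 library 1 alone gave 15 higher and 22 lower wall genes. Without Cd50 library 1 and Cd200 library 3, which held 1641 FPKM over the root surface and cortex genes, 14 wall genes were higher and 12 lower, and after rescaling by read sums 12 and 14. Histone and cell cycle genes had 3 of 219 higher and 13 lower (3 and 11 adjusted over the list alone; camera adjusted p = 0.0315; adjusted p = 0.888 with an estimated correlation), and 4 and 6 after rescaling by read sums. Cell division control protein 6 homolog (evm.TU.ctg59.219, chromosome 5, 76007594 to 76011647), which licenses DNA replication, fell from 31.5 ± 11.7 to 2.05 ± 1.06 FPKM. KINESIN LIGHT CHAIN-RELATED 2 (evm.TU.ctg635.210, chromosome 6, 70419245 to 70422074), not itself a cell cycle protein, fell from 146 ± 24.2 to 31.2 ± 12.2. Ribosomal protein genes had 4 of 338 higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.00274; adjusted p = 0.888 with an estimated correlation). They had 8 and 0 after rescaling by read sums, 7 and 0 without Cd50 library 1 and 2 and 0 without Cd50 library 1 and Cd200 library 3. S25-2 reached 8.82 ± 3.31 FPKM and the chloroplast protein L1 30.3 ± 10.4.

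Among transcription factors at Cd200, 16 of 93 NAC genes rose and 3 fell (16 and 3 adjusted over the list alone). Of the WRKY genes, 10 of 92 rose and 4 fell (11 and 5). Of the MYB genes, 16 of 224 rose and 13 fell (18 and 14). Ethylene genes had 15 of 154 higher and 15 lower (15 and 16 adjusted over the list alone). Abscisic acid and dehydration genes had 7 of 88 higher and 5 lower (9 and 8). Auxin genes had 10 of 133 higher and 2 lower (10 and 2). Pathogenesis-related proteins and chitinases had 14 of 121 higher and 10 lower (16 and 12 adjusted over the list alone). Heat shock proteins and chaperones had 2 of 222 higher and 7 lower (2 and 4). ABC transporters had 3 of 121 higher and 4 lower (3 and 4). Nitrate genes had 8 of 102 higher and 6 lower (8 and 7 adjusted over the list alone). Phosphate starvation genes had 5 of 70 higher and 4 lower (5 and 4). Aquaporins had 2 of 29 higher and 1 lower (2 and 1). Flavonoid genes had 2 of 95 higher and 10 lower (2 and 13 adjusted over the list alone). Photosynthesis genes had 2 of 31 higher and 1 lower (2 and 1). Hypoxia and fermentation genes had 0 of 44 higher and 2 lower (0 and 2), beside 8693 FPKM over the core fermentation genes in Cd200 library 3. After rescaling by read sums, 7 ABC transporters were higher and 4 lower, and 5 heat shock proteins were higher and 3 lower. MYB genes then had 26 higher and 12 lower, NAC genes 17 and 1, ethylene genes 18 and 10 and pathogenesis-related proteins 16 and 6. Without Cd50 library 1 and Cd200 library 3, flavonoid genes had 5 higher and 5 lower, ethylene genes 21 and 8, photosynthesis genes 0 and 2, pathogenesis-related proteins 17 and 5, ABC transporters 5 and 6 and heat shock proteins 4 and 5. When Cd50 library 1 alone was left out, auxin genes had 15 higher and 8 lower, abscisic acid genes 10 and 8, nitrate genes 9 and 10, ABC transporters 7 and 7 and heat shock proteins 4 and 9. Aquaporins then had 4 and 1, photosynthesis genes 4 and 1 and hypoxia and fermentation genes 0 and 4.

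At Cd200 limma called 2308 genes, 1128 higher and 1180 lower (48.9% higher), and after rescaling by read sums 1635 higher and 806 lower (67% higher; 66.4% with limma-voom). The count was 1139 without control library 3, 1402 without control library 4, 1175 without Cd200 library 2 and 1005 without Cd200 library 3. It rose to 2983 without Cd200 library 1.

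**Figure D3:**
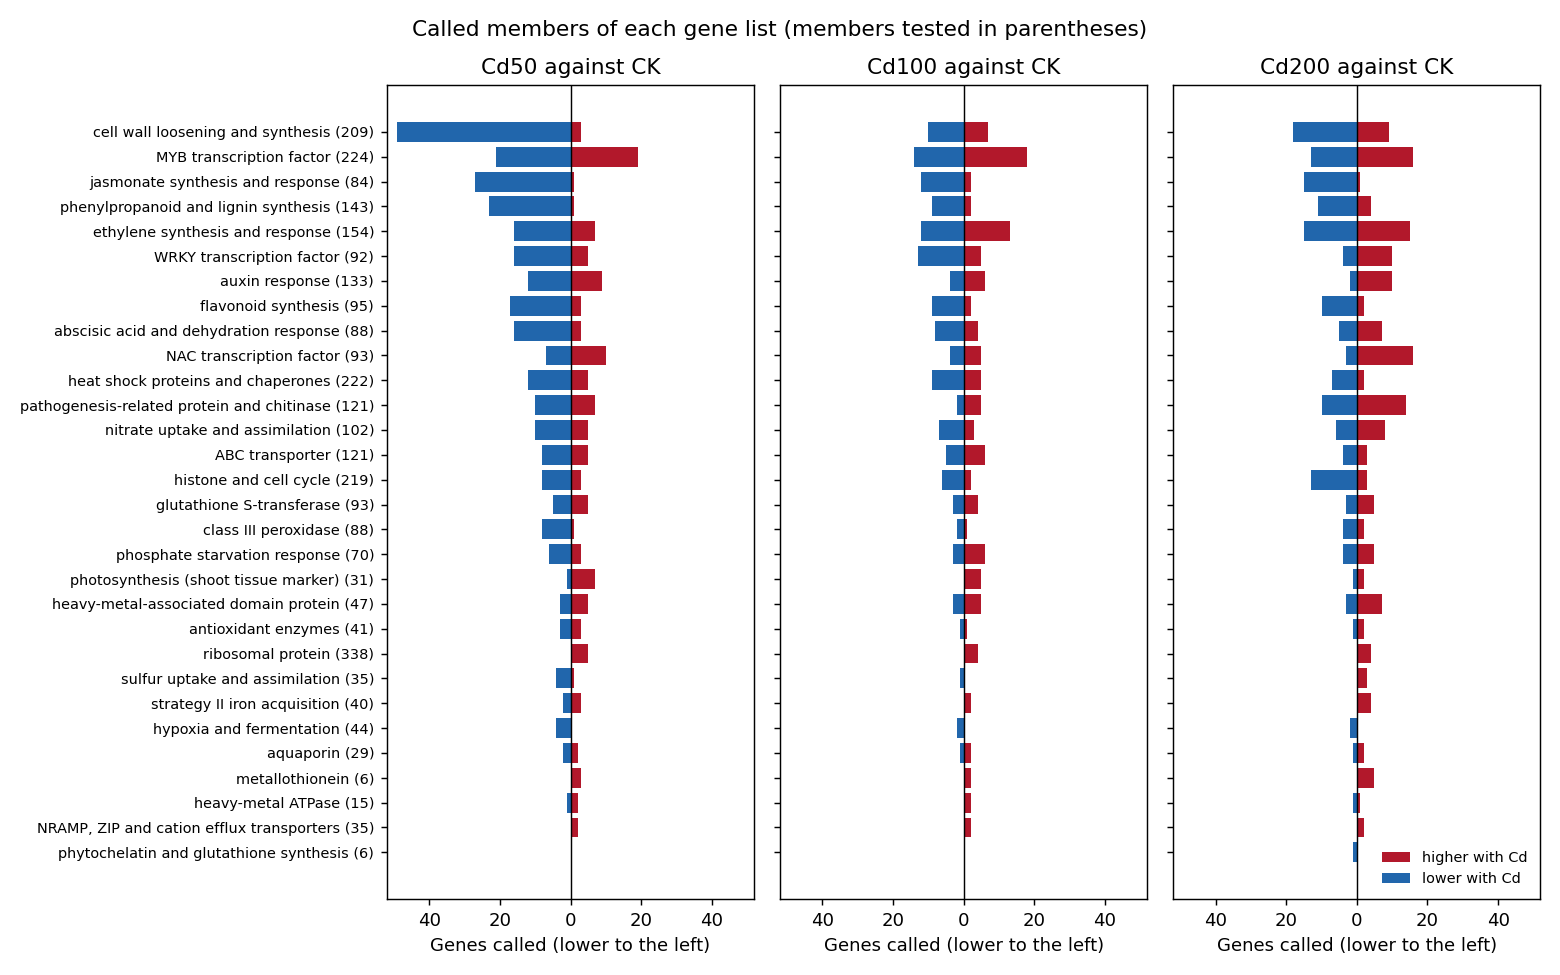
Bars give the number of genes called higher (right) or lower (left) with cadmium in each gene list, 1 panel per comparison with CK, with the members tested in parentheses. The cell wall list has 49 lower genes at Cd50, 10 at Cd100 and 18 at Cd200 on the authors' scaling, and 40 at Cd50 after rescaling by read sums; the jasmonate list has 27, 12 and 15.

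Few genes were called between the doses, each chosen here after its values were seen. 2-oxoglutarate-dependent dioxygenase 11 (evm.TU.ctg313.87, chromosome 1, 81187032 to 81188301) was higher at Cd100 (18.5 ± 1.17 FPKM, adjusted p = 0.037) and at Cd200 (19.4 ± 5.99, adjusted p = 0.043) than at Cd50 (4.31 ± 0.569). A gene without annotation (evm.TU.ctg17.111, chromosome 5, 16864046 to 16864258) was higher at Cd100 (124 ± 31.5 FPKM) than at Cd50 (12.2 ± 4.89; adjusted p = 0.037). Tricin synthase 1 (evm.TU.ctg575.118, chromosome 9, 63783491 to 63784546), a methyltransferase named for a grass flavone, was higher at Cd200 (11.1 ± 2.11) than at Cd100 (1.51 ± 0.810; adjusted p = 0.049). With limma these made 2 genes for Cd100 against Cd50, 1 for Cd200 against Cd100 and 1 for Cd200 against Cd50, while 2690, 2171 and 2026 genes had an unadjusted p under 0.05. Each count became 0 with limma-voom. The Cd100 against Cd50 count was 1, another gene, without Cd50 library 3 and 0 without any other single library of these groups. The Cd200 against Cd100 count was 0 without Cd100 library 1 or 3 or any Cd200 library. The Cd200 against Cd50 count was 0 without Cd50 library 1 or 2 or Cd200 library 1 or 3, 2 without Cd200 library 2, and 1, another gene, without Cd50 library 3.

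Genes called at several doses were called in the same direction. Of 3877 genes called at 1 dose or more, 1001 were called at all 3 doses, 376 higher and 625 lower, 1869 at 1 dose only, and 0 in opposite directions at any pair of doses. Opposite calls would need at least a 2-fold change each way from the same controls. Few genes were called between doses, so the count of 0 adds little. Metallothionein-like protein 4B, GSTU6 and YSL16 were among those named above as higher at all 3 doses, and DREB1F and REVEILLE 4 among those lower. Cd50 and Cd100 shared 429 higher and 867 lower genes (27.1 and 77.5 for independent lists, 0 and 0 in simulated unchanged groups). Cd50 and Cd200 shared 613 and 907 (39.7 and 82.1; 0 and 0). Cd100 and Cd200 shared 495 and 699 (33.7 and 51.1; 0 and 0). Unchanged groups gave hardly any calls, so the simulated counts of 0 do not measure how much of the sharing came from the common controls. Log2 changes correlated across genes with r = 0.775, 0.839 and 0.802 for these pairs, against 0.500, 0.501 and 0.500 in simulated unchanged groups with the same controls. They had the same sign for 78.6%, 81% and 79.5% of genes (66.7%, 66.7% and 66.6% simulated). Their covariance was 0.522, 0.587 and 0.510, beside 0.077 simulated. Genes are not independent replicates, the 3 control libraries were too few to split, and part of the excess may come from the shared controls. The number called at all 3 doses was 434 without control library 3, 423 without control library 4, 376 without Cd100 library 1, 611 without Cd100 library 2, 618 without Cd200 library 2 and 577 without Cd200 library 3.

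Across the 4 groups, the F test called 2413 genes that differed from the control at any dose, and the linear contrast over the dose order called 2200, 1147 rising and 1053 falling. The F count was 1183, 340 and 295 without control library 1, 3 and 4, 1491 without Cd50 library 2, 1512 without Cd100 library 1 and 1500 without Cd100 library 2. The trend count was 1401, 884 and 1014 without control library 1, 3 and 4, 875 without Cd200 library 2 and 769 without Cd200 library 3; a trend can arise from the step between the control and the lowest dose alone.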

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

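Rescaling by recovered reads, limma-voom, leaving out both Cd50 library 1 and Cd200 library 3, and camera without the trended variance were chosen after seeing the data. The 3 counts against the control moved by less than 1.5 times in every alternative other than leaving out a library. The balance of higher and lower genes turned with rescaling by read sums and with limma-voom, and not with median-ratio rescaling. Of 193 named gene values that were called, 139 stayed called under each alternative tried for them and 0 changed sign. Without control library 3, 32 were lost, without control library 4, 30, and without Cd100 library 1, 25 of 62. The rule picked called genes with large changes or small adjusted p. A change of sign was therefore unlikely from the start, and these shares need not hold for other calls. Of all 1882 genes called at Cd100, 478 stayed called without Cd100 library 1.

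The counts between doses (2, 1 and 1 for Cd100 against Cd50, Cd200 against Cd100 and Cd200 against Cd50) were 0, 0 and 0 with no filter, with quantile normalization, with the replicate block, with only the 2 groups compared, with limma-voom and without both Cd50 library 1 and Cd200 library 3. They were 1, 0 and 1 with a pseudocount of 0.1. The Cd200 against Cd100 count was 0 at a mean FPKM of at least 5 and with robust eBayes. After rescaling by read sums the counts against Cd50 were 0 and 0. The trend count without both libraries was 1444. Of the lists, 0, 0 and 0 passed at Cd50, Cd100 and Cd200 with an estimated correlation (1, 0 and 1 at an unadjusted p under 0.05), and 1, 0 and 1 with fry (7, 3 and 6 unadjusted), in place of 8, 3 and 5. Both passing with fry were metallothionein. Camera without the trended variance gave 8, 3 and 5.

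Leaving out each library in turn gave 1265 to 3027 genes for Cd50, 491 to 1549 for Cd100 and 1005 to 2983 for Cd200 against the control. Between doses it gave 0 to 1 for Cd100 against Cd50, 0 to 1 for Cd200 against Cd100 and 0 to 2 for Cd200 against Cd50. The F test gave 295 to 3238, the trend 769 to 2707 and the number called at all 3 doses 376 to 1318. Leaving out a library also removes a replicate, so lower counts follow in part from fewer samples. For the other moved values the cause was not tested.

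The column numbers, which may not be the original ones, gave no sign of pairing between the cadmium libraries. Deviations from group means cancel within a group, so the means for same and different numbers are not independent. Over 9 pairs of same-numbered cadmium libraries the deviations from group means correlated at -0.322 to 0.411 (mean -0.109; 0.055 for different numbers), and 2 of 9 libraries correlated best with their own number. With the replicate block the counts were 2292, 1422 and 1978 against the control, 1403 for the F test, 1579 for the trend and 807 at all 3 doses. The block also ended the calls of Nramp2 at Cd50 and of Peroxidase 2 and Ferredoxin-nitrite reductase at Cd100. With 12.42 to 17.71 M reads, 1 read on a 1 kb gene is worth up to 0.088 FPKM, so genes under about 1 FPKM rest on few reads.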

Other observations

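Clock-related genes moved in opposite directions. This group, which takes in REVEILLE 4 and REVEILLE 3 as named above, was chosen after its values were seen. Of 24 tested clock genes, 9 were called at 1 dose or more (37.5%, against 15.1% of all tested genes) and 5 at all 3 doses. REVEILLE 4, REVEILLE 3 and 1 gene named REVEILLE 6 (evm.TU.ctg378.112, chromosome 1, 13828938 to 13829986, 8.40 FPKM in CK and 0.0358, 0.197 and 0.280 at Cd50, Cd100 and Cd200) fell at every dose. REVEILLE 1 (evm.TU.ctg780.358, chromosome 8, 57710970 to 57713721) stood at 8.17 FPKM in CK and 30.8, 36.4 and 35.1 with cadmium, and another REVEILLE 6 (evm.TU.ctg488.29, chromosome 3, 1039459 to 1045892) at 9.29 and 27.3, 31.0 and 32.2; both rose at every dose. GIGANTEA (evm.TU.ctg9.4, chromosome 5, 6608730 to 6616978) was not called, at 165.7 FPKM in CK and 106, 106 and 97.2 with cadmium, nor was LATE ELONGATED HYPOCOTYL (evm.TU.ctg609.32, chromosome 9, 12133795 to 12137614), at 24.7 and 27.2, 29.4 and 27.9.

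The tests of the authors' scaling, of time of day, of a label exchange, of read depth and of shoot tissue were chosen only after the results were seen, though the bound for scaling was written before the rescaled counts were computed; the counts of splits were planned. The control separated from every dose while few genes were called between doses, where changes near 2-fold would mostly be missed. If the authors' library totals were the source of the separation, dividing by recovered reads should lower a count against the control below the count divided by 1.5. The lowest ratio was 1.058, but this rescaling also raised the median log2 change, which by itself can add calls. Of the 2696, 1882 and 2308 genes called at Cd50, Cd100 and Cd200, 2080, 1489 and 1933 were also called after that rescaling. Most calls therefore did not hinge on the choice between the authors' totals and read sums. Median-ratio rescaling gave 2683, 1872 and 2308 genes. It left the median log2 change of all genes at 0, 0.02 and -0.01, beside 0, 0.01 and -0.01 as deposited. It thus hardly altered the scaling, and its counts cannot test the authors' totals. The share of genes called higher depended on the rescaling used. Sampling the control at another time of day may contribute. Of the tested clock genes 37.5% were called, above all genes but below the 50% written as its mark. Those called were REVEILLE genes and PRR37. The genes named LHY, LATE ELONGATED HYPOCOTYL, PRR1, PRR73, PRR95, GIGANTEA and PCL1 were called at no dose, so the share does not decide the question. The labels give no sampling times. An effect of cadmium that is near its maximum at 50 mg/kg, and any handling that differed between control and treated pots, stay open and were not tested.

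Cd50 library 1 correlated best with Cd200 library 3 (r = 0.927) and not with its own group. This was not particular to it, as each Cd200 library also correlated best with a library of another dose. The best partner was Cd100 library 3 for Cd200 library 1 (0.952), Cd50 library 2 for Cd200 library 2 (0.959) and Cd100 library 2 for Cd200 library 3 (0.933). An exchange of labels between Cd50 and Cd200 would raise the mean correlation within both groups. Every exchange raised it within Cd50 (from 0.897 to 0.956 for Cd200 library 2) and lowered it within Cd200 (from 0.926 to at most 0.904), so a single wrong label or an exchange could not be told apart from a root sample that differs, for instance in fermentation genes. The depth of Cd50 library 1, 14.99 M reads, lay within the range of the other cadmium libraries, which argues against read depth.

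The photosynthesis list was higher at Cd50 and Cd100. Shoot tissue in the cadmium samples would bring in the transcripts most abundant in leaves, and 20 such transcripts gained 0.733 times as much summed FPKM as the 4 other called members at Cd50 (53.9 FPKM in CK and 81.4 in Cd50). At Cd100 the ratio was 0.09 (53.9 and 68.8 FPKM). Over single libraries it ran from -0.0974 to 1.48 at Cd50 and from 0.055 to 0.103 at Cd100, where early light-inducible proteins made up much of the gain, so a small share of shoot tissue could not be told apart from a change in the roots.

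Other splits of the same libraries were counted for each comparison. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. As many genes as in the real split were called in 1 split for Cd50 against CK (real 2696, highest other 1), 1 for Cd100 against CK (1882 and 1), 1 for Cd200 against CK (2308 and 0) and 1 for Cd100 against Cd50 (2 and 0). For Cd200 against Cd100 it was 2 splits (real 1, highest other 1), and for Cd200 against Cd50 also 2 (real 1, highest other 61). The split with 61 set Cd50 library 1 with Cd200 libraries 1 and 3 and points to a structure of the samples other than dose. For the F test 2 of 100 splits, the real one included, gave as many genes (real 2413, highest other 3072). For the trend it was 1 of 100, the real one (real 2200, highest other 1677). Both shares were under 0.05. Only 2 of the 99 drawn splits kept the control libraries together, so the shares bear on the separation of the control and not on dose. Both highest splits kept the 3 control libraries together. That of the F test mixed only Cd50 with Cd200, and that of the trend kept 2 of 3 libraries of each dose together. Splits that parted the control libraries gave at most 13 and 6 genes.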
